A study of Mus musculus with 14 samples.

How the data were processed

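Per the labels' protocols, bone marrow of 8-week-old female C57BL/6 mice was grown in M-CSF for 1 week, replated, and kept for 24 h in plain DMEM or in DMEM with EO771-conditioned medium and tumour lysate. RNA was purified on columns, and 200 ng of it was labelled with Cy3 for one-colour Agilent 8x60K mouse arrays. Per the submitters' processing notes, scans were read with Feature Extraction 10.7.3.1. Per the file headers, the deposited scanner output holds 1 signal intensity per spot after background subtraction and spatial detrending, with marks for spots above background, saturated or uneven. The deposited series matrix holds log2 values. They were checked here to be quantile normalized, with a median of 2.84 and a 75th percentile of 6.47 in every column, and they correlate with the log2 scanner intensities at 0.999 or more. How the authors chose probes or filtered genes is not given in the sources used here.

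The scanner intensities were the starting point: 14 arrays with 62976 spots each, 59305 of them not controls. Between 166 and 270 spots per array carry a mark for unevenness and were left out. 47 probes were dropped because no usable spot was left on some array. Spots of 1 probe were averaged, giving 55681 probes. Each array was scaled by subtracting the log2 of its 75th percentile (83.9 to 144 in signal) from the log2 signal. Gene symbols came from matching the probes' RefSeq accessions to a table of accessions and symbols: 28331 probes received 1 symbol, 21368 genes in all, and 27350 received none, of which 16194 target genome regions. The table belongs to a later genome assembly than the arrays' design, so no coordinates were used. A probe was kept when well above background on all arrays of at least 1 group (20208 probes), and the brightest probe stood for each gene. That left 15834 genes, 10974 of them with a symbol; unnamed probes were counted as genes of their own.

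Groups are genotype by medium, as the labels give them, and a title ending in -2 was read as a repeat array of the same replicate. That makes 11 replicates on 14 arrays. A model in limma 3.58.1 (R 4.3.3) fitted the 4 group means and a slide term, with arrays of 1 replicate as a random block (correlation 0.072), 9 residual degrees of freedom and 2.6 prior ones. Wherever an adjusted p is given for a gene it is from this fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts are tumour material against control within each genotype, transgenic against wild-type within each medium, and the difference between both responses. With 3 replicates or fewer in a group, SDs are rough guides only. The slope between the responses was set against 20 simulations of equal responses, with the fitted noise drawn for each gene on its own. Its SE is from a jackknife over replicates.

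Fixed lists of genes were tested with camera at a preset correlation between genes of 0.01, with adjustment over 27 lists, and again with the correlation estimated from the residuals. They cover lysosomes, autophagy, alternative and inflammatory activation, interferon, hypoxia, lipid metabolism, stress, cell division, matrix and markers of cell types, 570 genes in all with 564 on the array. At the preset correlation 43 of the 135 list tests passed, and with an estimated one 12 did. A count adjusted over the list alone repeats the adjustment among the list's members. Lists, groups, contrasts, thresholds and most alternatives were fixed before the data were examined. Slide column 4 as a term, leaving out the arrays of that column, and single slides for genes and lists were added later.

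Genes are named by a rule fixed at the same time: per contrast the 6 largest rises and falls among genes past the threshold with separated replicates, up to 3 passing members of each list, and a set of regulators and activation markers whatever their values. Of these, preference went to genes whose call survives leaving out any replicate. Some genes that the rule names are not reported here, though the counts include them. Where no array of a group lies above background, the fold is a lower bound: the bright group's mean is set against the mean, per array, of the dimmest signal well above background or the probe's own signal if higher. The list medians with dim genes at their bound use the same limit.

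The fit was tested on simulated data with 200 changed genes among 15834. In the wild-type response it recovered 29.0% of 1.5-fold, 64.5% of 2-fold and 93.0% of 4-fold changes, and 3.7% of its calls were false. For the transgene effect with tumour material it recovered 9.0%, 37.9% and 82.7%, with 6.2% false. A list of 30 genes shifted by 0.5 was found in 5 of 5 simulations, and 0 of 130 unshifted lists were called. The simulated noise was independent between genes and the lists were random genes. That result therefore cannot show how often lists of genes that move together are called falsely. In the data the estimated correlation reached 0.718 for neutrophil markers and 0.499 for cell cycle genes. Alternatives covered the threshold, the filter, probe choice, background correction, normalization, the deposited matrix, slide handling, repeat arrays, a replicate block, array weights, the samples in the fit and each replicate left out. The normexp background correction (offset 50) used the median signal of each spot, because the scanner output holds no mean signal. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.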

Results

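Expression was measured in macrophages grown from mouse bone marrow with M-CSF, from female C57BL/6 animals carrying LysM-driven Cre recombinase with a TFEB transgene (transgenic) or without it (wild-type). TFEB is a transcription factor that drives genes of lysosomes and autophagy. The cells then spent 24 h in plain medium (control) or in medium conditioned by EO771 mammary tumour cells with tumour lysate added (tumour material). These labels pose 2 questions: what tumour material changes in macrophages of each genotype, and what the transgene changes in each medium. The labels give 3 biological replicates per group. Analysed here are 14 one-colour microarrays: 4 of 3 wild-type control replicates, 4 of 3 wild-type tumour replicates, 3 of 3 transgenic control replicates and 3 of 2 transgenic tumour replicates. Transgenic tumour replicate 1 is not analysed here. Replicate 3 was measured on 2 arrays in 3 of the groups, and those arrays count as 1 replicate.

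Between 35.5% and 40.2% of spots lay well above background, the 75th percentile of the signal ran from 83.9 to 144, and 0 spots were saturated. Arrays of the wild-type control group correlated at 0.983 to 0.992, wild-type tumour at 0.989 to 0.994 and transgenic tumour at 0.979 to 0.992. Transgenic control replicate 1 stood apart, at 0.959 and 0.957 with the other replicates of its group, which correlated at 0.981. The 3 arrays in slide column 4, all transgenic (control replicates 1 and 2 and the repeat array of tumour replicate 3), took a larger multiplicative detrending in the scanner software, with a root mean square of 0.253 to 0.331 against 0.0964 to 0.126 elsewhere. The repeat array there correlated at 0.98 with the other array of its replicate, while transgenic tumour replicates 2 and 3 correlated at 0.992 outside that column. The arrays sat on 2 slides. The transgenic arrays are spread unevenly over them, so every comparison carries a slide term, and values from single slides are given beside it. That term rests in part on transgenic control replicates 1 and 2 (slide 1) against 3 (slide 2). Replicate 1 thus also affects the transgene effect with tumour material. Slide 2 holds 3 transgenic tumour arrays of 2 replicates and 1 array of each other group. In fits to slide 2 the repeat array counts as a sample of its own, and those 3 arrays alone give the spread. Adjusted p values from slide 2 are therefore rough guides. Values are log2 of signal over the array's 75th percentile. Each gene is represented by its brightest probe, and 15834 genes were tested.

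Tfeb itself came first. Its 1 probe was above background on every array, and whether that probe lies in the part carried by the transgene is not given in the sources used here. In control medium Tfeb stood at 1.17 ± 0.29 (SD, n = 3) in transgenic and 0.88 ± 0.08 (n = 3) in wild-type macrophages, a log2 difference of 0.31 (SE 0.13, adjusted p = 0.164; 0.43 within slide 1, 0.05 within slide 2). With tumour material the levels were −0.07 ± 0.10 (n = 2) and −0.68 ± 0.06 (n = 3), a difference of 0.69 (SE 0.16, adjusted p = 0.0264; 0.50 within slide 2). That call is lost without any of wild-type control replicate 3, wild-type tumour replicates 1, 2 or 3 and transgenic tumour replicates 2 or 3, with an adjusted p of up to 0.202. Tumour material lowered Tfeb in both genotypes, at −1.55 in wild-type (SE 0.12, adjusted p = 1.67e-06) and −1.16 in transgenic cells (SE 0.16, adjusted p = 0.000232).

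Among genes commonly placed downstream of TFEB, Gpnmb and Sqstm1 did not pass between genotypes: −0.01 (adjusted p = 0.965) and 0.09 (adjusted p = 0.799) in control medium, 0.47 (adjusted p = 0.0918) and 0.23 (adjusted p = 0.637) with tumour material. The related factor Tfe3 stood at −0.20 (adjusted p = 0.739) and 0.14 (adjusted p = 0.882). Mitf was at −0.46 in control medium (SE 0.09, adjusted p = 0.0077) and at 0.30 with tumour material (SE 0.11, adjusted p = 0.148); the former call is lost without wild-type control replicate 3 (adjusted p = 0.0708). Tumour material raised Mitf in transgenic cells by 0.56 (SE 0.11, adjusted p = 0.00237), against −0.20 in wild-type cells (SE 0.08, adjusted p = 0.0711, or 0.0461 without transgenic control replicate 1), and raised Tfec in both, by 2.47 (SE 0.17) and 1.83 (SE 0.13).

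How wild-type macrophages respond to tumour material is the largest comparison. Arg1, which encodes the arginase of alternatively activated macrophages, was below background on every control array and reached 6.56 ± 0.08 (SD, n = 3) with tumour material, a rise of at least 699-fold. Where every array of 1 of 2 compared groups is dim, the fold between them is given only as such a lower bound. The cystatin Csta2 rose at least 1310-fold, the growth factor G-CSF (Csf3) at least 251-fold and the prostaglandin synthase Ptgs2 at least 58.8-fold. Il6 rose from −2.78 ± 0.32 to 5.80 ± 0.15 (n = 3 each), by 8.59 (SE 0.15), though only 2 of 4 control arrays measured it. Il1b rose by 3.50 (SE 0.30), Nos2 by 7.86 (SE 0.30), and the anti-inflammatory cytokine Il10 by 3.28 (SE 0.19). The replicate values of both groups were fully separated for each of these genes.

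Other genes fell. Cdkn1c, a cell-cycle inhibitor, was at least 93.3-fold lower, the neutrophil granule gene Ngp at least 32.9-fold and the prostaglandin-degrading Hpgd at least 38.6-fold. The MHC class II genes H2-Eb1 and H2-Aa fell, at −4.37 (SE 0.59) and −3.37 (SE 0.68), and the fractalkine receptor Cx3cr1 fell by 3.77 (SE 0.31). The mannose receptor Mrc1 fell by 1.77 (SE 0.22) and the chitinase-like Chil3 fell by 2.14 (SE 0.37), both commonly used as markers of alternative activation.

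Inflammation and low-oxygen genes moved up together. Of 38 detected members of the inflammatory cytokine and chemokine list, 33 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 2.69 (2.70 within slide 1, 2.65 within slide 2; camera adjusted p = 3.26e-16, adjusted p = 0.00748 with an estimated correlation). Tnf rose by 3.08 (SE 0.17) and Cxcl10 by 4.09 (SE 0.48). The NF-kB target list had 17 of 24 rising and 1 falling (19 and 1 adjusted over the list alone), with Socs3 up by 4.93 (SE 0.34) and Ier3 by 3.39 (SE 0.32). Its median was 1.12 (1.02 within slide 1, 1.22 within slide 2; adjusted p = 9.5e-08, adjusted p = 0.0291 with an estimated correlation). Hypoxia and glycolysis genes rose in 22 of 29 and fell in 1 (22 and 1 adjusted over the list alone), among them Ak4 by 4.59 (SE 0.28), Egln3 by 3.57 (SE 0.16) and the lactate exporter Slc16a3 by 2.79 (SE 0.21). The hypoxia median was 1.09 (1.10 within slide 1, 1.07 within slide 2; adjusted p = 3.27e-08, adjusted p = 0.00261 with an estimated correlation).

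Interferon-stimulated genes rose in 31 of 36 and fell in 0 (32 and 0 adjusted over the list alone), for example Gbp5 by 2.96 (SE 0.49) and Isg20 by 2.37 (SE 0.31). The interferon median was 1.16, or 1.12 with dim genes at their bound (1.16 within slide 1, 1.14 within slide 2; adjusted p = 3.11e-10, adjusted p = 0.278 with an estimated correlation). M2-like markers split: 13 of 21 rose and 4 fell (13 and 4 adjusted over the list alone), with Socs2 at least 11-fold and Ccl17 at least 4.19-fold higher while Mrc1 and Chil3 fell. Their median was 0.88 (0.88 within slide 1, 0.88 within slide 2; adjusted p = 0.00091, adjusted p = 0.0284 with an estimated correlation). Matrix remodelling genes rose in 12 of 18 and fell in 2 (12 and 2 adjusted over the list alone), led by Serpinb2 at 8.11 (SE 0.64; 3 of 4 control arrays), Mmp13 at 6.13 (SE 0.21) and Mmp9 at 5.31 (SE 0.80). The matrix median was 1.13 (1.24 within slide 1, 0.96 within slide 2, 0.75 with normexp background correction; adjusted p = 0.00528, adjusted p = 0.196 with an estimated correlation).

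Sterol, lysosomal and granule genes went down. In the cholesterol synthesis list 0 of 24 rose and 20 fell (0 and 21 adjusted over the list alone), with Sqle at −3.45 (SE 0.74) and Idi1 at −3.14 (SE 0.25). The sterol median was −1.37 (−1.36 within slide 1, −1.401 within slide 2; adjusted p = 7.89e-12, adjusted p = 0.157 with an estimated correlation). Lysosomal hydrolases and membrane proteins rose in 6 of 45 and fell in 17 (6 and 17 adjusted over the list alone). Lysosomal lipase Lipa fell by 2.68 (SE 0.15) and Gusb fell by 1.62 (SE 0.15). The lysosomal median was −0.26 (−0.29 within slide 1, −0.20 within slide 2 with an adjusted p of 0.058; adjusted p = 0.01, adjusted p = 0.0496 with an estimated correlation). Cell cycle genes rose in 1 of 28 and fell in 14 (1 and 14 adjusted over the list alone), with a median of −0.80, or −0.70 with dim genes at their bound (−0.80 within slide 1, −0.62 within slide 2, −0.33 with normexp background correction; adjusted p = 0.00051, adjusted p = 0.628 with an estimated correlation). Neutrophil markers rose in 0 of 9 and fell in 7 (0 and 7 adjusted over the list alone), with Mpo at −3.92 (SE 0.35) and a median of −1.55 (−1.71 within slide 1, −1.24 within slide 2; adjusted p = 0.000194, adjusted p = 0.367 with an estimated correlation).

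The remaining lists did not pass, with adjusted p from 0.114 to 0.874. V-ATPase subunits rose in 0 and fell in 5 of 16 (0 and 5 adjusted over the list alone), and autophagy genes rose in 6 and fell in 1 of 36 (5 and 1). The MiT/TFE family and its partners rose in 2 and fell in 4 of 15 (2 and 4), Tfec among the risen at 1.83 (SE 0.13). Counts for NRF2 targets were 7 and 3 of 21 (7 and 3), for LXR and PPAR targets 7 and 7 of 21 (7 and 7), and for ER stress genes 10 and 5 of 27 (11 and 6). Antigen presentation genes rose in 6 and fell in 6 of 19 (8 and 7), with a median of 0.07 but a mean of −0.52 and a test pointing down.

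Cell type markers were followed as well. General macrophage markers rose in 6 and fell in 4 of 18 (6 and 5 adjusted over the list alone), dendritic cell markers in 3 and 1 of 5, and osteoclast markers in 1 and 4 of 7. T and NK cell markers moved in 0 and 1 of 5, B cell markers in 0 and 1 of 2, mast cell markers in 0 and 0 of 4, erythroid markers in 0 and 1 of 3, and endothelial markers in 1 and 1 of 3. Median and mean differ in sign for general macrophage markers (0.01 and −0.07) and endothelial markers (0.03 and −0.10). Of fibroblast markers 2 of 6 rose, Lum at least 36.0-fold among them, with a median of −0.13 and a mean of 1.53. The only epithelial marker detected, Lcn2, rose by 2.65 (SE 0.49).

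Across all genes, limma found 3667 higher and 2653 lower with tumour material, 6320 in all at an adjusted p under 0.05, of which 1228 and 1107 changed at least 2-fold. The share of rises depends on the scaling. It was 58% here, 48.6% with quantile normalization (3077 higher and 3253 lower) and 48.7% with the deposited matrix. Replicates of both groups did not overlap for 9189 genes (58%), where chance gives 10%. Without wild-type tumour replicate 3 the count was 3961, and within slide 2, with 1 array of each wild-type group, it was 771.

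**Figure D1:**
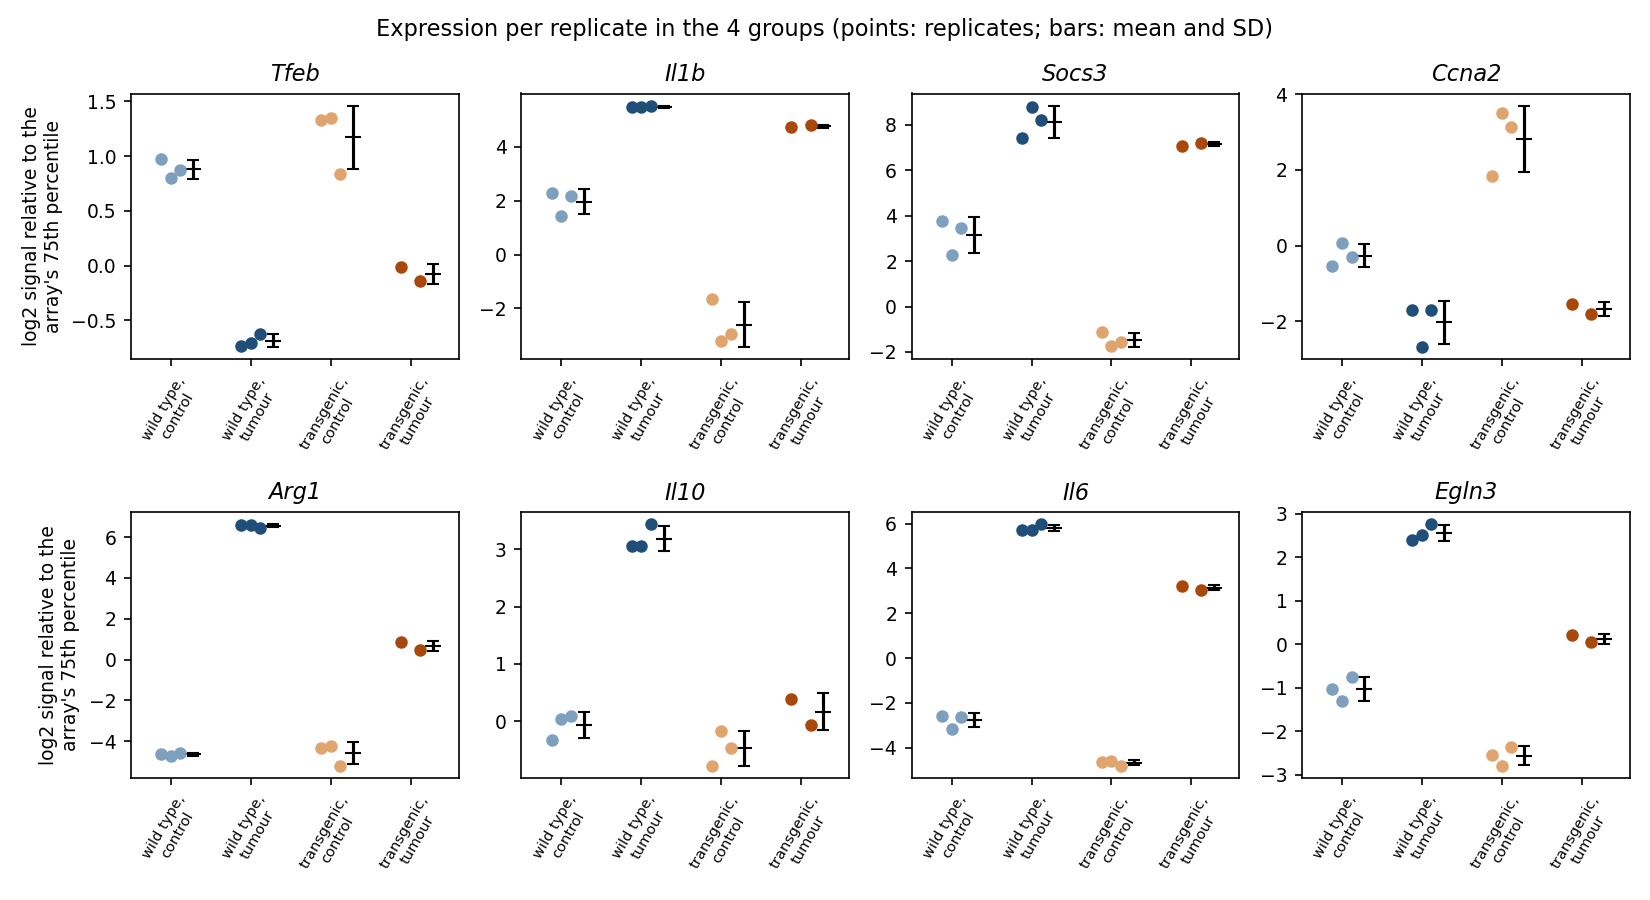
Levels of Tfeb, Il1b, Socs3, Ccna2, Arg1, Il10, Il6 and Egln3 in each replicate of the groups, with mean and SD. Values are log2 of signal over the array's 75th percentile.

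In plain medium 17 of 28 cell cycle genes were higher in transgenic cells and 7 of 38 inflammatory genes lower, though neither list passed with an estimated correlation (adjusted p = 0.0993 and 0.186). The mitotic kinase Pbk was at least 9.39-fold higher, the spindle genes Aunip and Ska1 at least 7.93-fold and at least 3.62-fold. Ccna2 rose from −0.27 ± 0.31 in wild-type to 2.83 ± 0.88 in transgenic cells (SD, n = 3 each), by 3.08 (SE 0.36; 2.94 within slide 1, 3.46 within slide 2). Il1b went from 1.96 ± 0.45 to −2.61 ± 0.83 (n = 3 each), lower at −4.60 (SE 0.32; −4.39 within slide 1, −5.12 within slide 2), with 1 of 3 transgenic arrays above background. Socs3, the feedback inhibitor of cytokine signalling, was lower, at −4.72 (SE 0.37; −4.61 within slide 1, −4.97 within slide 2).

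The secreted peroxidase Gpx3 was higher by 3.70 (SE 0.53), the iron exporter Slc40a1 by 1.29 (SE 0.12) and the lectin Clec10a by 1.26 (SE 0.16). Lower were the protease inhibitor Spint1 (at least 15.8-fold), the carboxylate transporter Slc13a3 (at least 8.61-fold), Flrt3 (at least 10.3-fold), Il6 (at least 1.68-fold) and the IL-4 receptor Il4ra (−1.61, SE 0.24). These are values of the brightest probe, and another probe showed less: −2.174 in Spint1, −0.885 in Flrt3 and −0.828 in Il4ra. The microglial and macrophage genes Cx3cr1, Itgam and C1qa were lower, at −1.92 (SE 0.33), −1.38 (SE 0.19) and −1.03 (SE 0.13). The 3 probes of Itgam ran from −1.58 to −0.16. Of 18 detected general macrophage markers these 3 alone passed, and the list did not (median −0.09, camera adjusted p = 0.116). Il10 at −0.46 (adjusted p = 0.179), Tnf at −0.08 (adjusted p = 0.839), Nos2 at −0.58 (adjusted p = 0.281), Mrc1 at −0.48 (adjusted p = 0.228) and Chil3 at −0.01 (adjusted p = 0.986) did not pass, and Arg1 was dim in both genotypes.

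Cell cycle genes were higher in 17 of 28 and lower in 0 (24 and 0 adjusted over the list alone), Nusap1 among them by 3.09 (SE 0.38; 1 of 4 wild-type arrays). Their median was 1.57, or 1.51 with dim genes at their bound (1.56 within slide 1, 1.96 within slide 2; adjusted p = 1.02e-20, adjusted p = 0.0993 with an estimated correlation). Neutrophil markers were higher in 4 of 9 and lower in 0 (4 and 0 adjusted over the list alone): Mpo by 2.63 (SE 0.38), Ctsg by 2.10 (SE 0.33) and Elane by 1.74 (SE 0.32), all made by granulocyte precursors. Their median was 0.35 (1.02 within slide 1, −0.03 within slide 2; adjusted p = 0.0168, adjusted p = 0.5 with an estimated correlation). That median rests on transgenic control replicate 1. Without replicate 1 it was −0.35 (camera adjusted p = 0.717). It was 1.21 and 1.09 without replicate 2 or 3 of that group, and 0.64 without wild-type control replicate 3. With slide column 4 as a term it was 0.15 (adjusted p = 0.0485), and without the arrays of that column −0.23 (adjusted p = 0.473). In replicate 1, Ltf stood at 6.17 against 2.53 and 3.56 in replicates 2 and 3, and Mpo at 5.85 against 3.88 and 4.22. The MHC class II gene H2-Aa stood at −0.08 against 3.92 and 3.98. The 3 precursor genes were not raised in replicate 1 alone: Mpo stood at 1.8 to 2.55 in wild-type control replicates. Elane stood at 3.34 and 3.19 in transgenic replicates 2 and 3 (1.69 to 2.17 in wild-type), and Ctsg at 2.22 and 2.19 (0.33 to 1). Ltf and Ngp lay below wild-type in replicates 2 and 3.

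Inflammatory genes were higher in 0 of 38 and lower in 7 (1 and 11 adjusted over the list alone), with a median of −0.38 (−0.43 within slide 1 with an adjusted p of 0.0823, −0.55 within slide 2, −0.58 with slide column 4 as a term; adjusted p = 0.00297, adjusted p = 0.186 with an estimated correlation). NF-kB targets were higher in 0 of 24 and lower in 7 (1 and 8 adjusted over the list alone), with a median of −0.40 (−0.39 within slide 1, −0.42 within slide 2; adjusted p = 9.33e-05, adjusted p = 0.0993 with an estimated correlation). Hypoxia genes were higher in 0 of 29 and lower in 5 (0 and 8 adjusted over the list alone), with Egln3 at −1.61 (SE 0.17; 1 of 3 transgenic arrays above background). The hypoxia median was −0.30 (−0.26 within slide 1, −0.45 within slide 2; adjusted p = 0.000672, adjusted p = 0.0462 with an estimated correlation). ER stress and amino acid response genes were higher in 0 of 27 and lower in 6 (0 and 9 adjusted over the list alone), including the serine synthesis gene Phgdh at −1.36 (SE 0.16). Their median was −0.35 (−0.32 within slide 1, −0.18 within slide 2 with an adjusted p of 0.186; adjusted p = 9.33e-05, adjusted p = 0.0993 with an estimated correlation). With slide column 4 as a term the ER stress value was −0.18 (adjusted p = 0.000574), and without the arrays of that column the call is lost (−0.22, adjusted p = 0.0505).

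Lysosomal genes were higher in 0 of 45 and lower in 8 (0 and 10 adjusted over the list alone). Their median was −0.19 (−0.21 within slide 1, −0.23 within slide 2 with an adjusted p of 0.23; adjusted p = 0.00452, adjusted p = 0.062 with an estimated correlation). This call is lost with normexp background correction (−0.13, adjusted p = 0.501). Autophagy genes were higher in 1 of 36 and lower in 0 (1 and 0 adjusted over the list alone), with a median of 0.13 (0.17 within slide 1, 0.08 within slide 2 with an adjusted p of 0.748; adjusted p = 0.0354, adjusted p = 0.16 with an estimated correlation). Leaving out wild-type control replicate 2, transgenic control replicate 1 (median 0.02) or 2, or transgenic tumour replicate 3 loses the autophagy call, with an adjusted p of up to 0.102, as do slide column 4 as a term (adjusted p = 0.193), leaving out its arrays (0.05, adjusted p = 0.473) and normexp background correction (adjusted p = 0.216). V-ATPase subunits were higher in 0 of 16 and lower in 1 (0 and 2 adjusted over the list alone; median −0.19, adjusted p = 0.174), and the MiT/TFE family in 0 and 2 of 15 (0 and 3; median −0.08, adjusted p = 0.116).

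Antigen presentation genes were higher in 0 of 19 and lower in 4 (0 and 7 adjusted over the list alone), with H2-DMa at −1.37 (SE 0.16). Their median was −0.17 (−0.19 within slide 1 with an adjusted p of 0.0823, −0.36 within slide 2; adjusted p = 0.00761, adjusted p = 0.16 with an estimated correlation). It was −0.44 without transgenic control replicate 1, −0.07 without replicate 2 (adjusted p = 0.0567), −0.30 with slide column 4 as a term, −0.28 without its arrays and −0.09 with normexp background correction. Matrix genes were higher in 2 of 18 and lower in 6 (2 and 8 adjusted over the list alone), with Mmp14 at −1.55 (SE 0.23), with a median of −0.92 (−0.78 within slide 1 with an adjusted p of 0.0795, −1.17 within slide 2, −0.38 with normexp background correction; adjusted p = 0.00552, adjusted p = 0.16 with an estimated correlation), or −0.59 without wild-type control replicate 3. Fibroblast markers, higher in 0 of 6 and lower in 1 (0 and 2 adjusted over the list alone), had a median of −1.89 (adjusted p = 0.0628). The collagen gene Col3a1 was lower, at −4.08 (SE 1.03, adjusted p = 0.0307; 1 of 3 transgenic and 3 of 4 wild-type arrays above background), and its call is lost without wild-type control replicate 3 (adjusted p = 0.217) and without 5 others of the 11 replicates. M2-like markers were higher in 2 of 21 and lower in 4 (4 and 4 adjusted over the list alone; median −0.01, adjusted p = 0.846). The other lists did not pass (adjusted p from 0.0628 to 0.946), and for LXR and PPAR targets (median −0.06, mean 0.01), mast cell markers (−0.11 and 0.16) and osteoclast markers (−0.19 and 0.06) median and mean differ in sign.

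By limma 568 genes were higher and 830 lower in transgenic cells in control medium, 1398 in all, of which 253 and 380 changed at least 2-fold. Replicates did not overlap for 3401 genes (21.5%), where chance gives 10%. The count fell to 405 without wild-type control replicate 3, 887 without wild-type control replicate 1 and 790 without transgenic tumour replicate 3, and was 2432 without transgenic control replicate 1. Slide 2 alone gave 0 by limma, with 2124 genes at an unadjusted p under 0.05.

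With tumour material, transgenic macrophages held far less Arg1 and Il10 than wild-type ones. Arg1 stood at 0.66 ± 0.26 (SD, n = 2) against 6.56 ± 0.08 (n = 3), lower at −5.66 (SE 0.22; −5.68 within slide 2). Il10 stood at 0.16 ± 0.32 (n = 2) against 3.19 ± 0.22 (n = 3), lower at −3.28 (SE 0.24; −3.39 within slide 2). Il6 was lower, at −2.71 (SE 0.19; −2.78 within slide 2), as were the IL-10 family cytokine Il19, at least 15.4-fold and the incretin receptor Gipr, at least 15.7-fold. Also lower were Csf3, at −1.79 (SE 0.22), Ptgs2, at −1.73 (SE 0.25), and the chemokine Cxcl5, at −4.21 (SE 0.84, adjusted p = 0.0139). These 3 calls are lost without wild-type tumour replicate 3, and those of Ptgs2 and Cxcl5 also without transgenic tumour replicate 3. Several inflammatory genes did not pass: Tnf at −0.27 (adjusted p = 0.568), Il1b at −0.67 (adjusted p = 0.393), Nos2 at −0.94 (adjusted p = 0.22), Ccl2 at −0.72 (adjusted p = 0.748) and Cxcl10 at −0.09 (adjusted p = 0.961). Ccl2 itself stood at 8.3 and 8.33 in transgenic and at 8.44 to 8.5 in wild-type replicates, so most of its value comes from the slide term.

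H19, Actc1 and Myh3 were lower in transgenic cells in both media. In control medium H19 stood at −0.71 ± 1.11 against 2.09 ± 0.18 in wild-type (SD, n = 3 each), lower at −2.90 (SE 0.49, adjusted p = 0.00374). Actc1 stood at −1.82 ± 1.36 against 1.18 ± 0.31 (n = 3 each; 2 of 3 transgenic arrays above background), lower at −3.06 (SE 0.49, adjusted p = 0.00282). Myh3 stood at −2.09 ± 0.67 against 1.03 ± 0.12 (n = 3 each; 1 of 3 transgenic arrays), lower at −3.19 (SE 0.35, adjusted p = 0.000274). With tumour material H19 was lower, at −6.22 (SE 0.59; −6.25 within slide 2; 1 of 3 transgenic arrays above background), Actc1 at least 13.8-fold and Myh3 at least 11.2-fold. The lipase inhibitor Angptl4 was lower, at −2.50 (SE 0.23; −2.52 within slide 2). Higher were Gpr162 by 3.24 (SE 0.39; 3.36 within slide 2), the fatty-acid binding protein Fabp4 by 1.62 (SE 0.18; 1.66 within slide 2), Timp2 by 1.65 (SE 0.22) and Slc40a1 by 1.06 (SE 0.14). Mrc1 at 0.88 (adjusted p = 0.115) and Chil3 at −0.58 (adjusted p = 0.57) did not pass.

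Hypoxia genes were higher in 0 of 29 and lower in 9 (0 and 17 adjusted over the list alone), with Egln3 at −2.63 (SE 0.20; −2.67 within slide 2) and Bnip3 at −2.01 (SE 0.26; −1.92 within slide 2). The hypoxia median was −0.65 (−0.51 within slide 2; adjusted p = 2.82e-10, adjusted p = 0.000914 with an estimated correlation). Vegfa, a target of the same pathway, stood at −0.13 (adjusted p = 0.948), or −0.35 with its other probe. Its replicates stood at 0.22 and 0.26 in transgenic and at 0.65 to 0.75 in wild-type cells. The slide term thus moved its value towards 0. That term is affected by transgenic control replicate 1, where Vegfa stood at 2.83 against −0.31 and −0.35 in replicates 2 and 3. Cholesterol synthesis genes were higher in 9 of 24 and lower in 0 (14 and 0 adjusted over the list alone). Their median was 0.85 (0.95 within slide 2; adjusted p = 5.98e-13, adjusted p = 0.191 with an estimated correlation). Inflammatory genes were higher in 0 of 38 and lower in 6 (2 and 10 adjusted over the list alone), with a median of −0.44 (−0.28 within slide 2, −0.29 without the column 4 arrays, −0.28 with normexp background correction; adjusted p = 0.000541, adjusted p = 0.191 with an estimated correlation).

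Fibroblast markers were higher in 0 of 6 and lower in 1 (0 and 3 adjusted over the list alone), the proteoglycan Lum at −4.43 (SE 0.16; −4.55 within slide 2; 2 of 3 transgenic arrays above background). Their median was −2.89, or −2.45 with dim genes at their bound (−1.88 within slide 2, −1.32 with normexp background correction; adjusted p = 0.000133, adjusted p = 0.191 with an estimated correlation). Interferon-stimulated genes were higher in 0 of 36 and lower in 0 (0 and 0 adjusted over the list alone), with a median of 0.25 (0.17 within slide 2; adjusted p = 0.0391, adjusted p = 0.786 with an estimated correlation). Their call is lost without any of wild-type tumour replicates 1 or 2, transgenic control replicates 1 (0.11) or 3 (0.16) and transgenic tumour replicate 3 (0.10), with an adjusted p of up to 0.444, with slide column 4 as a term (0.11, adjusted p = 0.312) and without its arrays (0.10, adjusted p = 0.0663).

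M2-like markers were higher in 1 of 21 and lower in 2 (3 and 4 adjusted over the list alone), with a median of −0.39 (adjusted p = 0.0925). It was −0.44 within slide 2, which holds 1 wild-type tumour array. With slide column 4 as a term it was −0.33 (adjusted p = 0.0227), and without its arrays −0.35 (adjusted p = 0.0061). The value was −0.49 without transgenic control replicate 1 (adjusted p = 0.0145), −0.15 without wild-type tumour replicate 3 and −0.17 without transgenic tumour replicate 3. Lysosomal genes were higher in 1 of 45 and lower in 0 (1 and 0 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0925). That became 0.18 without transgenic control replicate 1 (adjusted p = 0.0402), 0.11 without transgenic control replicate 2 and 0.05 without transgenic tumour replicate 3. The lysosomal value was 0.07 with slide column 4 as a term (adjusted p = 0.269), 0.10 without its arrays (adjusted p = 0.129) and 0.10 within slide 2. NF-kB targets had a median of −0.27 (adjusted p = 0.0781) and cell cycle genes 0.08 (adjusted p = 0.797). The other lists did not pass (adjusted p up to 0.948). Median and mean differ in sign for ER stress genes (−0.02 and 0.04), matrix genes (0.02 and −0.39), neutrophil markers (0.19 and −0.13) and endothelial markers (0.02 and −0.09).

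By limma 312 genes were higher and 405 lower in transgenic cells with tumour material, 717 in all, of which 185 and 268 changed at least 2-fold. Replicates did not overlap for 7602 genes (48%), where chance gives 20% with 2 replicates against 3 and no difference between slides. That condition is not met here: these values carry no slide term, and all transgenic tumour arrays sit on slide 2. The count was 130 without transgenic tumour replicate 3, 134 without wild-type tumour replicate 3, 428 without wild-type control replicate 3, 475 without wild-type tumour replicate 1 and 1600 without transgenic control replicate 1. Slide 2, which holds all transgenic tumour arrays and 1 wild-type tumour array, gave 0 alone by limma, with 1770 genes at an unadjusted p under 0.05. Of the genes called in both media, 71 were higher in both (11.2 if independent), 154 lower in both (21.2 if independent) and 29 opposite. The groups compared share no arrays, but both effects share the slide term of 1 fit. The values if independent are therefore rough guides.

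Transgenic macrophages also answered tumour material strongly. The chemokine Cxcl3 rose at least 461-fold, Csta2 at least 439-fold, Il6 at least 101-fold and Csf3 at least 99.9-fold. Socs3 rose by 8.55 (SE 0.45), Nos2 by 7.50 (SE 0.39), Tnf by 2.89 (SE 0.22) and Il1b by 7.44 (SE 0.39), the last from 1 of 3 control arrays above background to 3 of 3. Arg1 rose at least 18.3-fold, and Il10, at 0.46 (SE 0.24, adjusted p = 0.2), did not pass. Falling genes included the granule genes Mpo, at −5.62 (SE 0.46), and Ngp, at least 39.1-fold, the neuronal activity gene Npas4, at least 22.8-fold, Angptl4, at −5.09 (SE 0.23), and Chil3, at −2.70 (SE 0.49).

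Inflammatory genes rose in 30 of 38 and fell in 0 (32 and 0 adjusted over the list alone), with a median of 2.79, or 2.68 with dim genes at their bound (2.81 within slide 2, 1.71 with normexp background correction; adjusted p = 2.32e-19, adjusted p = 0.00559 with an estimated correlation). NF-kB targets rose in 18 of 24 and fell in 0 (18 and 0 adjusted over the list alone), with a median of 1.29 (1.30 within slide 2; adjusted p = 2.84e-10, adjusted p = 0.0148 with an estimated correlation). Hypoxia genes rose in 18 of 29 and fell in 1 (21 and 1 adjusted over the list alone), with Ak4 up by 3.05 (SE 0.37; 2 of 3 control arrays above background) and a median of 0.83 (0.75 within slide 2; adjusted p = 7.07e-06, adjusted p = 0.00559 with an estimated correlation). Interferon-stimulated genes rose in 27 of 36 and fell in 0 (32 and 0 adjusted over the list alone), Gbp7 by 3.55 (SE 0.40), with a median of 1.28 (1.47 within slide 2; adjusted p = 2.07e-12, adjusted p = 0.227 with an estimated correlation).

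Matrix genes rose in 10 of 18 and fell in 1 (10 and 1 adjusted over the list alone), with Mmp8 up by 4.50 (SE 0.60) and a median of 1.85 (1.62 within slide 2, 1.10 with normexp background correction; adjusted p = 5.44e-05, adjusted p = 0.0853 with an estimated correlation). M2-like markers rose in 8 of 21 and fell in 2 (8 and 2 adjusted over the list alone), with a median of 0.44 (0.56 within slide 2 with an adjusted p of 0.0875; adjusted p = 0.0213, adjusted p = 0.0878 with an estimated correlation). Without transgenic control replicate 1 the M2-like value was 0.35 (adjusted p = 0.0965), without replicate 2 of that group 0.66, without the column 4 arrays 0.56 (adjusted p = 0.134) and with normexp background correction 0.25. Cell cycle genes rose in 1 of 28 and fell in 24 (1 and 25 adjusted over the list alone), with Ccna2 at −4.75 (SE 0.43). Their median was −2.51, or −2.38 with dim genes at their bound (−2.78 within slide 2; adjusted p = 2.18e-14, adjusted p = 0.163 with an estimated correlation). Neutrophil markers fell in 9 of 9 (9 adjusted over the list alone), with a median of −2.83 (−2.60 within slide 2; adjusted p = 1.2e-08, adjusted p = 0.163 with an estimated correlation). Cholesterol synthesis genes rose in 0 of 24 and fell in 10 (0 and 11 adjusted over the list alone), with a median of −0.76 (−0.74 within slide 2; adjusted p = 3.86e-05, adjusted p = 0.439 with an estimated correlation). Lysosomal genes rose in 9 of 45 and fell in 7 (9 and 7 adjusted over the list alone; median 0.16, adjusted p = 0.801, and 0.13 without transgenic tumour replicate 3). The other lists did not pass (adjusted p from 0.0728). Median and mean differ in sign for the MiT/TFE family (−0.09 and 0.11), LXR and PPAR targets (0.13 and −0.12) and erythroid markers (0.10 and −0.65).

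By limma 2391 genes rose and 1609 fell in transgenic cells, 4000 in all, of which 1203 and 878 changed at least 2-fold. Rises made up 59.8%, against 50.7% with quantile normalization (1971 higher and 1916 lower) and 50.6% with the deposited matrix. Replicates did not overlap for 8012 genes (50.6%), where chance would give 20% if slides did not differ. That count carries no slide term either. The count was 2317 without transgenic tumour replicate 3 and 1771 within slide 2. Both genotypes raised 2017 genes (553.7 if independent) and lowered 1197 (269.6 if independent), with 27 opposite. Their responses share no arrays of the groups compared, but they do share the slide term, so the values if independent are rough guides.

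**Figure D2:**
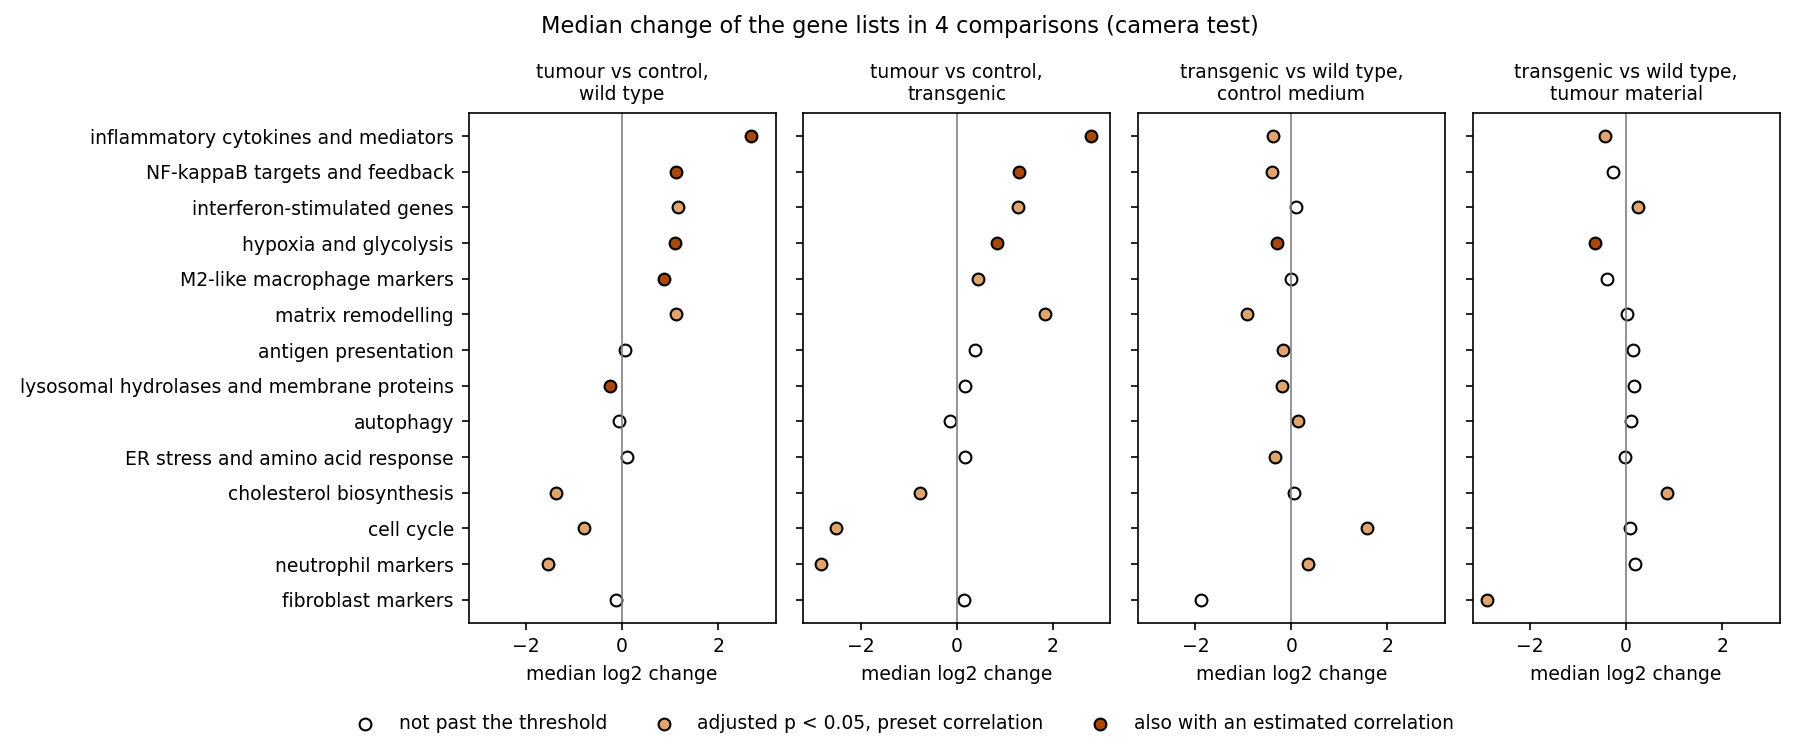
Median log2 difference of 14 gene lists in 4 comparisons. Open marks did not pass, light marks passed at the preset correlation and dark marks also with an estimated one.

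Arg1 and Il10 are among the genes whose responses differ. Arg1, Gipr and Lum rose less in transgenic cells (adjusted p = 1.27e-06, 8.98e-05 and 1.27e-06). All 3 were dim in either genotype in control medium, and Gipr also in transgenic cells with tumour material, so only the direction of their differences counts. The Il10 difference was −2.82 (SE 0.31; −2.80 within slide 2; adjusted p = 0.000821). Angptl4 differed at −2.91 (SE 0.30; −3.30 within slide 2). Nxpe5 at 3.83 (SE 0.26; 4.28 within slide 2), Phgdh at 2.83 (SE 0.25; 2.62 within slide 2) and the glutathione-degrading Chac1 at 1.91 (SE 0.18; 2.03 within slide 2) went the other way. These 8 of 37 named genes kept their call with any replicate left out. Il1b at 3.93 (SE 0.49, adjusted p = 0.00209), up to 0.0595 with a replicate left out, did not keep it. Its genotypes differed mainly in control medium, with 1.44 to 2.28 in wild-type and −3.21 to −1.65 in transgenic replicates. With tumour material they stood at 5.46 to 5.53 and at 4.73 and 4.81. Il6 at −0.78 (adjusted p = 0.167), Tnf at −0.19 (adjusted p = 0.877), Nos2 at −0.36 (adjusted p = 0.862) and Mrc1 at 1.36 (adjusted p = 0.0945) did not pass.

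Lysosomal genes differed together although 0 of 45 passed in either direction (0 and 0 adjusted over the list alone), with a median of 0.30 (0.26 within slide 2; adjusted p = 1.32e-06, adjusted p = 0.00557 with an estimated correlation). Hypoxia genes were higher in 0 of 29 and lower in 1 (0 and 2 adjusted over the list alone), with a median of −0.40 (−0.30 within slide 2, −0.26 with normexp background correction; adjusted p = 0.000764, adjusted p = 0.0267 with an estimated correlation), or −0.26 without wild-type control replicate 1 and −0.25 without transgenic tumour replicate 2. Cholesterol synthesis genes were higher in 2 of 24 and lower in 0 (10 and 0 adjusted over the list alone), with a median of 0.85 (0.59 within slide 2, 0.56 with normexp background correction; adjusted p = 3.01e-10, adjusted p = 0.18 with an estimated correlation). Cell cycle genes were higher in 0 of 28 and lower in 10 (0 and 16 adjusted over the list alone). Their median was −1.85 (−2.03 within slide 2, −1.21 with normexp background correction). The camera adjusted p was 2.78e-17, and 0.18 with an estimated correlation. Between genotypes their median was 1.57 in control medium and 0.08 with tumour material, so the genotypes differed mainly in control medium. Antigen presentation genes were higher in 2 of 19 and lower in 0 (2 and 0 adjusted over the list alone), with a median of 0.46 (0.50 within slide 2, 0.26 with normexp background correction; adjusted p = 0.000146, adjusted p = 0.07 with an estimated correlation), or 0.28 without transgenic control replicate 2.

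Neutrophil markers were higher in 0 of 9 and lower in 0 (0 and 6 adjusted over the list alone), with a median of −1.23 (−1.22 within slide 2; adjusted p = 0.00105, adjusted p = 0.435 with an estimated correlation), or −0.62 without wild-type tumour replicate 3. Without the column 4 arrays this call is lost (−0.79, adjusted p = 0.0703). ER stress genes were higher in 3 of 27 and lower in 0 (3 and 0 adjusted over the list alone), with a median of 0.09 (0.03 within slide 2 with an adjusted p of 0.389; adjusted p = 0.00105, adjusted p = 0.18 with an estimated correlation). The ER stress value was 0.16 without wild-type control replicate 3, 0.17 and 0.32 without transgenic control replicates 2 and 3, and 0.31 without transgenic tumour replicate 3. V-ATPase subunits were higher in 0 of 16 and lower in 0 (1 and 0 adjusted over the list alone), with a median of 0.18 (0.09 within slide 2 with an adjusted p of 0.286; adjusted p = 0.036, adjusted p = 0.439 with an estimated correlation). Their call is lost without any of wild-type control replicate 2, wild-type tumour replicates 1 or 3, transgenic control replicate 1 and transgenic tumour replicate 2 (adjusted p up to 0.206), with slide column 4 as a term (adjusted p = 0.0584), without its arrays (adjusted p = 0.0942) and with normexp background correction (0.11, adjusted p = 0.0569), and the value was 0.33 without transgenic control replicate 3. Matrix genes were higher in 3 of 18 and lower in 0 (6 and 0 adjusted over the list alone), with a median of 0.56 (0.40 within slide 2; adjusted p = 0.036, adjusted p = 0.312 with an estimated correlation). The matrix call is lost without any of wild-type control replicates 1 or 3, transgenic control replicates 2 or 3 and transgenic tumour replicate 3, with an adjusted p of up to 0.214, with slide column 4 as a term (adjusted p = 0.0584) and with normexp background correction (0.17, adjusted p = 0.105). M2-like markers were higher in 3 of 21 and lower in 3 (5 and 7 adjusted over the list alone; median −0.56, adjusted p = 0.0761), or −0.21 without wild-type tumour replicate 3 and −0.26 without transgenic control replicate 1. Inflammatory genes were higher in 2 of 38 and lower in 1 (2 and 1 adjusted over the list alone; median −0.20, adjusted p = 0.505). For erythroid markers, which did not pass, median and mean differ in sign (0.07 and −0.06).

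By limma 161 genes differed upward and 147 downward between the responses, 308 in all. Of these, 168 responded less in transgenic cells and 140 more, and 110 of the 308 had the opposite sign there. Over all genes the transgenic response followed the wild-type one with a slope of 0.82 (jackknife SE 0.05), against 0.93 (0.92 to 0.94) in 20 simulations of equal responses, and a Pearson correlation of 0.82 against 0.90. The simulated noise was normal, independent between genes and equal in all groups. It leaves out deviations that genes of 1 array share, as in transgenic control replicate 1, so the simulated range may be too narrow. The count was 43 without transgenic tumour replicate 3, 44 without wild-type tumour replicate 3, 158 and 181 without wild-type control replicates 3 and 1, 192 without wild-type tumour replicate 1 and 1009 without transgenic control replicate 1. Slide 2 alone gave 0 by limma, with 1380 genes at an unadjusted p under 0.05.

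**Figure D3:**
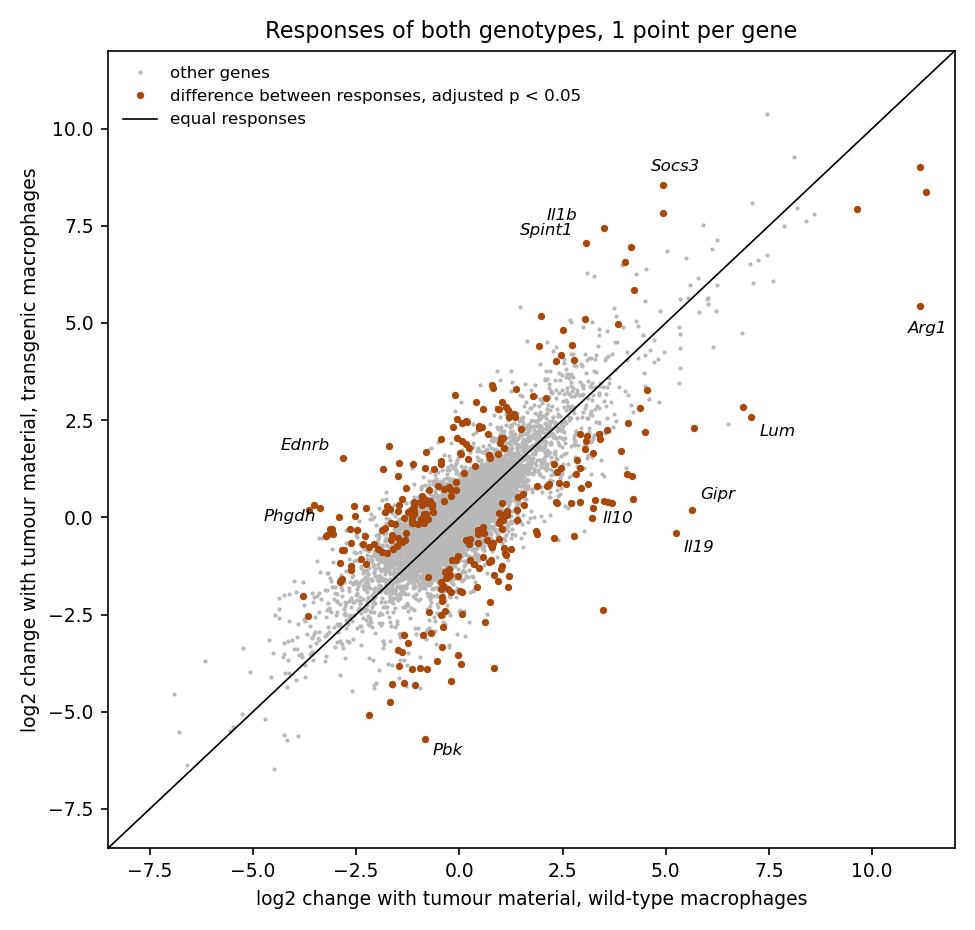
Response to tumour material in transgenic against wild-type macrophages for every gene, with the line of equal responses. Coloured are the 308 genes whose responses differ.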

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

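Of the tests of explanations below, the medians of the added progenitor and muscle lists were set down before their result was seen; the others, those within single slides included, were chosen after it. The tested difference between the responses of the genotypes to tumour material set 308 genes apart, and the named ones are given here because that test passed for each of them. The log2 change with tumour material in transgenic macrophages minus that in wild-type ones, whatever the direction of either, was above 0 for Ednrb (4.36), Spint1 (3.99), Il1b (3.93), Kmo (3.84), Nxpe5 (3.83), Socs3 (3.62), Phgdh (2.83), Lck (2.47), Csf1 (2.11), Egr2 (2.07), H2-DMa (2.04), Chac1 (1.91), Fabp4 (1.86), Mmp12 (1.78), Mmp14 (1.73), H2-DMb1 (1.65), Spp1 (1.46), Dhcr7 (1.44), Cd40 (1.35), Asns (1.29) and Mitf (0.76). It was below 0 for Cd300e (−5.86), Arg1 (−5.73), Il19 (−5.63), Gipr (−5.45), Pbk (−4.87), Sapcd2 (−4.73), Lum (−4.48), Birc5 (−3.16), Ccnb2 (−3.14), Ccna2 (−3.07), Angptl4 (−2.91), Il10 (−2.82), Bnip3 (−1.74), Csf3 (−1.70) and Hilpda (−1.65). Of these, 8 kept their call whichever replicate was left out: Nxpe5, Arg1, Gipr, Il10, Angptl4, Phgdh, Chac1 and Lum. Spint1, Kmo, Cd300e, Arg1, Il19, Gipr, Pbk, Sapcd2, Lum and Csf3 were below background on every array of at least 1 group, so only the direction of their differences counts and the sizes rest on signal near background.

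Cell cycle genes were higher in transgenic than in wild-type macrophages in control medium, a list call that is lost with an estimated correlation (adjusted p = 0.0993). With slide column 4 as a term, which takes out what 2 of the 3 transgenic control arrays share by position, the list's median was 1.77 (SE 0.26, adjusted p = 1.53e-21), which argues against position as the whole cause. Within slide 1 it was 1.56 (SE 0.28) and within slide 2, with 1 array per group, 1.96 (SE 0.32). These SEs are over the list's genes, which move together, so the arrays of slide 1 count for more: against the mean of the wild-type ones there, the list's median was 0.88 and 1.93 on the transgenic arrays and −0.10 to 0.15 on the wild-type ones. That argues against a difference between slides. Progenitors left in the transgenic cultures may contribute: the progenitor list stood at 0.89 (SE 0.47, camera p = 0.0166, p = 0.112 with an estimated correlation; 12 of 21 genes detected), so this stays open. Against it as the whole cause, progenitor genes stood at 1.498 (SE 0.91) in replicate 1 and at 0.20 (SE 0.23) and 0.22 (SE 0.18) in replicates 2 and 3, where cell cycle genes stood highest, at 1.94 (SE 0.28) and 2.13 (SE 0.27) against 0.96 (SE 0.23).

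H19, Actc1 and Myh3 were lower in transgenic cultures in both media. They are expressed in developing muscle, and muscle cells carried along with the wild-type bone marrow could bring them. An added list of other muscle genes, of which 2 of 8 were lower in control medium and 0 of 8 with tumour material, had medians of −0.20 (SE 0.19) in control medium and −0.29 (SE 0.15) with tumour material. Within slide 2 the latter was −0.28 (SE 0.17). With only 8 of 32 members above background, muscle cells and an effect of the genotype cannot be told apart. Slides are another matter. Within slide 1 in control medium, both transgenic arrays lay below the 3 wild-type ones, with mean differences of −3.38 in H19, −3.81 in Actc1 and −3.49 in Myh3, and arrays of 1 group differed by at most 0.81. Within slide 2 the 3 genes were lower in both media as well, which argues against a difference between slides. In control medium, with 1 array per group there, the differences were smaller: −1.71 in H19, −1.27 in Actc1 and −2.42 in Myh3. Both transgenic arrays of slide 1 sit in slide column 4, and that position was not tested for these genes.

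Hypoxia and glycolysis genes were lower in transgenic macrophages with tumour material. Part of this was there in control medium, where their median was −0.30, so a weaker dose of the tumour material can only concern the response. The list lost 36.7% of its response, and a loss of that share would set the responses of 31 interferon-stimulated genes apart by −0.54. They differed by 0.14, in the opposite direction, which argues against a uniformly weaker stimulus as the whole cause. The SE of 0.06 is over genes that move together (estimated correlation 0.451 over the list), so it understates the spread. The hypoxia medians of both responses, 1.09 and 0.83, imply a smaller loss than 36.7%, so −0.54 is only a rough benchmark. The hypoxia median was −0.65 (SE 0.17) with the slide term and −0.51 (SE 0.18) within slide 2, which holds 1 wild-type tumour array. Within that limit, both values argue against slides as the whole cause. With no slide term it was −0.55 (SE 0.17). That value would carry any difference between slides, so it cannot decide this. An effect of the transgene on these genes may remain as a hypothesis, found and examined on the same arrays, and a difference in cell density or oxygen between cultures was not tested.

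For the number of genes past the threshold, 3 replicates against 3 make 10 splits, too few splits for a share under 0.05. The wild-type response gave 6320 in the real split and at most 1 gene in any other. The transgene effect in control medium gave 1398 in the real split and at most 44 in any other. The split with 44 groups wild-type control replicates 1 and 3 with transgenic control replicate 1. Every other split mixes both groups on each side, so a real difference widens the spread and lowers the count. These counts therefore decide nothing about chance.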

How the results depend on the processing

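Slide column 4 as a term, leaving out its arrays, and single slides for genes and lists were chosen after the data were seen. With a fold of at least 2 required as well, the counts were 2335 (wild-type response), 633 (transgene effect in control medium), 453 (with tumour material) and 2081 (transgenic response). Without a filter on dim probes 36699 genes were tested, the median of all genes shifted to −0.10, 0.26 and 0.13 in control medium, the transgenic response and the difference, and the counts were 848 for the control-medium effect, 442 for the effect with tumour material and 163 for the difference.

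Counts moved with the handling of slides and repeats, and the cause was not tested. With no slide term the effect with tumour material gave 1114. Slide 2 alone, where only the transgenic tumour arrays leave degrees of freedom, gave 771, 0, 0, 1771 and 0 by limma for the wild-type response, both transgene effects, the transgenic response and the difference (2124, 1770 and 1380 at an unadjusted p under 0.05 where the count was 0). Averaged repeat arrays with the share on slide 2 as a covariate gave 173 (tumour material), 2658 (transgenic response) and 89 (difference). Averaged with no slide term they gave 767 (control medium) and 171 (difference), and with repeat arrays left out the counts were 215 (tumour material) and 131 (difference). Fitting only the groups compared gave 488 (control medium) and 802 (transgenic response). Array weights gave 3900 (tumour material) and 804 (difference).

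Slide column 4 as a term gave 634, 449 and 199 for both transgene effects and the difference, and leaving out its arrays gave 1582 (tumour material) and 826 (difference). List tests passed 12 times with an estimated correlation, against 43, and 88 times by fry in its mixed form. With each replicate left out in turn, counts ran from 3961 to 7431 (wild-type response), 405 to 2432 (control medium), 130 to 1600 (tumour material), 2317 to 5030 (transgenic response) and 43 to 1009 (difference), list tests from 41 to 51 and the slope from 0.77 to 0.85. The lowest counts lacked replicate 3 of the wild-type control, wild-type tumour or transgenic tumour group, and the highest lacked transgenic control replicate 1; a lone remaining transgenic tumour replicate is assumed to vary like the other groups. Background correction by normexp split the control-medium effect 722 higher and 616 lower (54% against 40.6% higher) and the difference 93 and 129 (41.9% against 52.3%). With it the lysosomal list lost its call in control medium (−0.13, adjusted p = 0.501), as did autophagy (adjusted p = 0.216), and in the difference V-ATPase subunits (adjusted p = 0.0569) and matrix genes (adjusted p = 0.105), while lysosomal genes with tumour material (0.15, adjusted p = 0.0222) and M2-like markers in the difference (−0.53, adjusted p = 0.0478) gained one. Of 43 called lists it shrank 15 medians by more than 1.5 times, among them cell cycle genes in the wild-type response (−0.33), matrix genes in control medium (−0.38) and in the difference (0.17), and fibroblast markers with tumour material (−1.32).

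A replicate block, which treats equal replicate numbers as paired, gave 713 for the difference, 276 of them shared with the 308. Correlations of deviations between groups ran from −0.48 to 0.16 for equal numbers and from −0.24 to 0.31 for others. With tumour material the 2 shared numbers stood at 0.16 and 0.12, the others at −0.16 to 0.05. As no pairing shows overall and the labels give none, the samples were not paired. Vegfa reversed in the transgenic response, to 0.58 under the replicate block (adjusted p = 0.0144), 0.56 without the column 4 arrays (adjusted p = 0.0257) and 0.56 without transgenic control replicate 1 (adjusted p = 0.00614). In control medium Vegfa reversed to −0.70 without the column 4 arrays (adjusted p = 0.0287) and to −0.67 without transgenic control replicate 1 (adjusted p = 0.00277). With each replicate left out, Vegfa ran from −0.67 to 1.10 in control medium and from −1.07 to 0.56 in the transgenic response. Clec9a reversed in the wild-type response within slide 2 alone, at −0.91 (adjusted p = 0.263). The cause was not tested.

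Of 305 calls on named genes, 106 kept their call under every setting tried on single genes, and only 1 reversed its direction under any. These settings did not include the filter, probe choice, averaged repeats or array weights. Slide 2 alone kept no call on a transgene effect or on the difference, so all 106 belong to the responses to tumour material. The deposited matrix and quantile normalization each kept 296 and weakened 9, normexp kept 261 and weakened 44, no slide term kept 294 and weakened 11, and slide column 4 as a term kept 259 and weakened 46. Slide 2 alone kept 119, weakened 185 and reversed 1, and with each replicate left out in turn 2948 stayed and 407 weakened. Signal over background sets a limit of its own: genes dim on every array of a group have only bounds, and with 35.5% to 40.2% of spots well above background most low transcripts went untested.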

Other observations

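Macrophages of transgenic control replicate 1 differ from the others of their group in more than granule genes. Against the wild-type control mean, its neutrophil markers stood at 2.66 (SE 0.68), those of replicates 2 and 3 at −0.33 (SE 0.84) and −0.28 (SE 0.87). Antigen presentation genes stood at 0.11 (SE 0.32) in replicate 1, at −0.54 (SE 0.16) in replicate 2 and at −0.42 (SE 0.07) in replicate 3. The chemokine Ccl2 was at 1.55 in replicate 1 and at 6.15 and 5.99 in the others, Cd74 at 3.39 against 6.51 and 6.87, and the protease gene Mmp9 at 0.63 against −4.34 and −3.56.

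2 genes typical of fibroblasts varied among wild-type control replicates. The collagen gene Col3a1 stood at −3.21 in replicate 2 and 1.46 in replicate 3, and the proteoglycan Dcn at 2.61, −2.44 and 2.74 in replicates 1, 2 and 3. No test was run on this pattern.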
